A study of Mus musculus with 9 samples.

How the data were processed

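RNA was measured in 9 EL4 tumours, 5 labelled Vec and 4 labelled HVEM-KO. EL4 is a mouse T-cell lymphoma line, and HVEM is the protein of the gene Tnfrsf14. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a SMARTER mRNA-Seq kit. The labels give no batch, day, animal or pairing. They do not say whether each library came from its own animal, so the p-values measure the spread between these libraries.

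The authors deposited 1 table of raw counts per gene, with 56923 Ensembl mouse gene identifiers and 9 columns that match the labels. The aligner, the counting program and the annotation are not given in the sources used here. The build was mm10, per the submitters' processing notes. Total counts ran from 5532155 to 8205620 per library. The sources used here name no molecular identifiers, and reads copied by PCR are not independent molecules, so floors from counts cover counting error only. No pair of libraries agreed within sampling noise. The lowest chi-square per degree of freedom was 12.8, between Vec 1 and Vec 5.

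The row names did not match what the rows held. In the deposited counts the rows of Eef1a1, Tmsb4x, Mki67, Col1a1 and Cd74 had 0 reads in all 9 libraries, and the row of Actb had 166, while that of Gapdh had 13002. Of 127 genes of respiration, glycolysis, ribosomes, growth and the cell cycle, 49 had fewer than 10 reads by deposited name. Only 35 versioned identifiers were in the GENCODE vM21 annotation of GRCm38, and 52073 were there without their version. Rows without an identifier there held 1.55% of the reads. Mitochondrial rows, taken under their own names, held 9.51% of the reads.

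The locus each nuclear row counted was therefore inferred from the counts. The GRCm38 exons of each row were moved along the chromosome by a displacement of up to 2 Mb in steps of 250 bp. A hidden Markov model with a switch penalty of 20 took the displacement, constant over a stretch, at which the overlap with exons of protein-coding genes best accounted for the row totals. Ribosomal protein genes, and olfactory, vomeronasal, zinc finger and similar families, formed classes of their own in the count model. It found 104 stretches on 20 chromosomes. The log-likelihood gain over a count model by exon length alone was 10462 at the fitted displacements and -11505 without displacement. The median size of the displacement was 138000 bp over rows. In windows of 120 rows, the median correlation across rows between overlap and count was 0.65 at the best displacement and 0.16 without. Both comparisons favour the fitted displacement by construction. Genes are not independent replicates in these correlations. No converted coordinate is reported.

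A row was placed on a gene when the posterior was at least 0.99, at least 100 bp and 90% of its coding overlap lay on that gene, and a shift of 250 bp either way gave the same gene. This placed 5961 rows with 32.3% of the reads on 4697 genes, mostly other genes than the row's own. Of these rows, 732 lay on their own gene. Another 30042 rows, with 35.7% of the reads, had no single protein-coding locus. The position of 12475 rows was uncertain (14.0% of the reads), and the locus of 2010 depended on the 250 bp (6.87%). A placed row covers part of a gene's exons, so levels are compared between libraries within a row and never between genes. Strand made no clear difference, with a median of 612 reads per kb of overlap on the same strand and 681 on the opposite strand, so a gene and an antisense partner cannot be told apart. Rows on near-identical families (H2, Gbp, Oas, Ly6 and Klr genes) can hold reads of a relative.

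The inference was tested on simulated data. On 3 chromosomes with 6029 rows, 97.7% of rows were found within 1000 bp of the simulated displacement. The counts were drawn from the classes fitted on the real table, at displacements smaller than the largest fitted one (1932750 bp). This recovery tests the search, and not the count model or the real placements. With counts shuffled among rows the gain per row was 0.0235, against at least 0.139 in every stretch that holds a gene named here. The posterior reached 0.99 for 100% of rows with shuffled counts, so it does not guard against a wrong stretch on its own. For 363 pairs of rows placed on the same gene, the median correlation of their deviations from the group means was 0.64. For 2295 pairs of neighbouring rows on different genes it was 0.23. For the 31 genes of the same housekeeping lists with a placed row, the placed row with most reads had a median total of 10480 reads. By deposited name the median was 21, over all 127 genes. The comparison is thus between unlike sets of genes and rows, and is not fully independent of the fit.

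Rows were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the filterByExpr filter, robust quasi-likelihood F tests and Benjamini-Hochberg adjustment over 11521 rows at a false discovery rate of 0.05. All 9 libraries entered without covariates. The SE of a log2 fold change was its size divided by the square root of F. Fold changes are HVEM-KO over Vec. Values per library are CPM, counts scaled to 1e6 per TMM-scaled library, as mean ± SD. On simulated counts for this comparison, 33.7% of 95 rows changed by log2 1 and 82.0% of 89 rows changed by log2 2 were called, and 6.96% of calls were false.

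The comparison, the tests, 44 gene lists and the rule for named genes were fixed before the data were examined. The locus inference, its switch penalty and 250 bp check, and the choice of which 11 lists to describe gene by gene were made after seeing the data. Lists with at least 5 tested members (17 lists) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. In simulated lists of 8 rows, 10 of 10 lists moved by log2 0.5 and 0 of 30 unmoved lists were called. The simulated rows were drawn independently of one another. In the real lists past the threshold the estimated correlation ran from 0.316 to 0.805, so the simulation does not cover false calls from correlated members. A list member was represented by the row with most reads whose coding overlap lay to 90% on genes of the list, also after a shift of 250 bp. A row over a pair of adjacent members was kept as that pair (Cd3d/Cd3g, H2-Aa/H2-Ab1, Gbp3/Gbp5 and Myh1/Myh4). The rows for C1qc, H2-DMb2 and Tap1 stayed on genes of their list under the shift but not on 1 gene. A list score is the mean log2 CPM of its members with a prior count of 2. The rule named the members of the HVEM network, the genes past the threshold with separate groups (up to 10 per direction), 5 genes of smallest p per direction where fewer passed, at a mean log2 CPM of at least 1 and without predicted genes and receptor segments, and up to 4 members of smallest p of each list described. It added the 3 most abundant members of each cell type list described. Some genes that the rule takes are not reported here.

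The alternatives were DESeq2 size factors, library size alone, no low-count filter, at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma voom with quality weights, a fold of at least 2, leaving out predicted genes and receptor segments, and leaving out each library. Leaving out Vec 1 and Vec 5 together, and finding list members by the deposited names, were added after seeing the data. Chance was judged on 100 of the 126 splits of the libraries into 5 and 4, and for DESeq2 on 30 of them. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.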

Results

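Gene expression was measured by RNA sequencing in 9 EL4 tumours, 5 from Vec cells and 4 from HVEM-KO cells. The study asks how HVEM on leukaemia cells bears on CD8 T cells, and the comparison is between the 2 kinds of tumour. Total counts were 8008123, 5674867, 8205620, 6530477 and 6347705 in Vec 1 to 5 and 5611976, 6318802, 6254256 and 5532155 in HVEM-KO 1 to 4. Gene names below are those of the locus a row was placed on from the counts, not the deposited names, and rest on that inference.

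**Figure D1:**
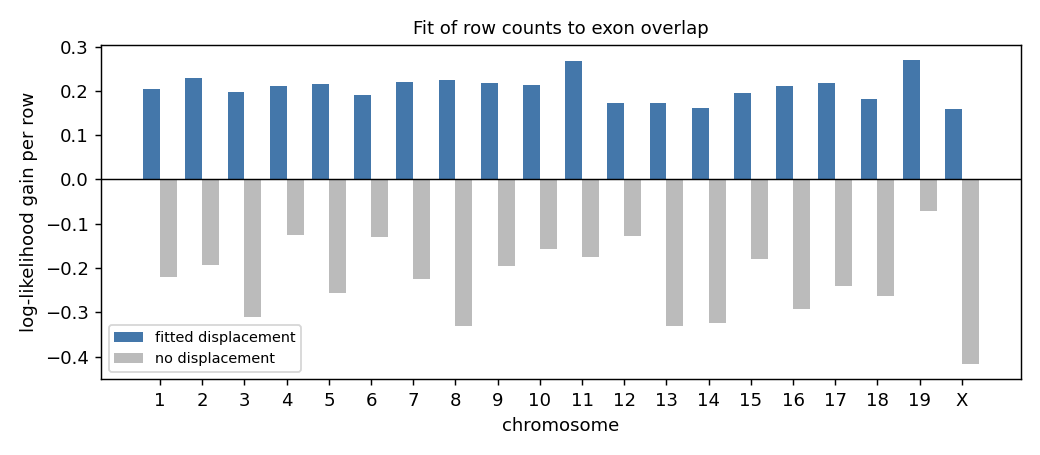
Log-likelihood gain per row (vertical axis) of the fit between row counts and exon overlap on each chromosome (horizontal axis), at the fitted displacement (blue bars) and without displacement (grey bars). The displacement was fitted to raise this gain and could be 0, so the blue bars are no test of it.

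The targeted gene could not be followed. Tnfrsf14 (ENSMUSG00000042333), which encodes HVEM, lies on chromosome 4 from 154921933 to 154928563 in GRCm38, on the minus strand. The row deposited under its identifier had 1 read, in Vec 5, and 0 in the other libraries, and no row was placed on the gene. That row was at or under the floor of 3 counts (0.366 to 0.542 CPM per library) in both groups, but its name need not be what it counted. The level of Tnfrsf14 was therefore not measured in either group. No fold is given, and the labels were not checked by the targeted gene.

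Of the other members of the HVEM network, 3 had a placed row. Btla, an inhibitory receptor that binds HVEM, was at 3.25 ± 1.98 CPM (SD, n = 5) in Vec and 0.910 ± 0.343 CPM (SD, n = 4) in HVEM-KO tumours. Tnfsf14, which encodes the HVEM ligand LIGHT, was at 8.18 ± 6.09 CPM in Vec and 17.6 ± 6.53 CPM in HVEM-KO tumours. Tnfrsf1a, a receptor for TNF, was at 77.2 ± 33.6 and 131 ± 25.6 CPM. The log2 fold changes were -1.83 ± 0.53 (SE), 1.11 ± 0.48 and 0.77 ± 0.29. Over all rows 0 of the 3 passed (edgeR's quasi-likelihood test, adjusted p = 0.353, adjusted p = 0.450 and adjusted p = 0.425), and 3 of 3 passed adjusted over the list alone (adjusted p = 0.0141, adjusted p = 0.0394 and adjusted p = 0.0296). Vec 1 and Vec 5, which stood apart from the other libraries, were the lowest of the 9 for Tnfsf14 (3.01 and 2.91 CPM) and Tnfrsf1a (43.36 and 43.47 CPM). The rows that passed the low-count filter with all 9 libraries were fitted again without both. The log2 fold changes were then -1.64 for Btla, 0.60 for Tnfsf14 and 0.40 for Tnfrsf1a. Btla alone passed adjusted over the list alone (edgeR, adjusted p = 0.0417, adjusted p = 0.145 and adjusted p = 0.0835). Its row failed the filter when that was applied without Vec 1 and Vec 5, so this call rests on the filter with all libraries. The row placed on Btla overlapped 321 bp of its exons, on the opposite strand, and held 139 reads in all. In GRCm38, Btla lies on chromosome 16 from 45224315 to 45257670 and Tnfsf14 on chromosome 17 from 57189492 to 57194177.

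Among placed genes with a mean log2 CPM of at least 1, without predicted genes and receptor segments, those of smallest p in the comparison of Vec and HVEM-KO tumours were Wif1, Fcamr and Fam155a among those lower in HVEM-KO tumours and Insrr and Padi4 among those higher, and 0 of them passed. The edgeR quasi-likelihood test called 0 of 11521 rows, with 1226 rows at an unadjusted p under 0.05. Most other splits of the libraries gave fewer such rows, but some gave more, up to 2451 for Vec 2 with HVEM-KO 1, 2 and 3. DESeq2 called 83 rows, 15 higher and 68 lower, and limma voom called 1. Without a low-count filter 307 rows passed, those of Btla, Tnfrsf1a and Tnfsf14 among them, but not that of Wif1. Wif1, a secreted inhibitor of Wnt signalling, was at 105 ± 45.5 CPM in Vec and 15.9 ± 11.5 CPM in HVEM-KO tumours (log2 fold change -2.72 ± 0.47, adjusted p = 0.171). DESeq2 gave it an adjusted p of 1.83e-06, the lowest over the alternatives, which reached 0.717 without Vec 1 and Vec 5. Fcamr, a receptor for IgM and IgA, had a log2 fold change of -1.98 ± 0.34 and Fam155a one of -0.82 ± 0.15 (adjusted p = 0.171 for both). Rnf19a, an E3 ubiquitin ligase, and Alms1, a centrosome protein, were at -0.72 ± 0.14 and -0.87 ± 0.19 (adjusted p = 0.284). Both were placed on rows of their own identifiers, that of Alms1 at a displacement of -23000 bp.

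Among genes with higher values in HVEM-KO tumours, Padi4, which converts arginine to citrulline in histones, was at 67.8 ± 14.4 CPM in Vec and 162 ± 64.8 CPM in HVEM-KO tumours (log2 fold change 1.25 ± 0.28, adjusted p = 0.291). It reached an adjusted p of 0.0178 with DESeq2 and 0.0495 without HVEM-KO 2, in a range over the alternatives from 9.48e-09 without a low-count filter to 0.717 without Vec 1 and Vec 5. Bcl2l11, which encodes the pro-apoptotic protein BIM, was at 31.5 ± 8.27 and 53.3 ± 6.62 CPM (0.76 ± 0.20, adjusted p = 0.310). Rbm47, an RNA-binding protein, had a log2 fold change of 0.98 ± 0.25 (adjusted p = 0.307). The low-count genes Insrr and Hoxb8 had log2 fold changes of 1.75 ± 0.38 and 1.73 ± 0.40 (adjusted p = 0.284 and 0.294). Of the 5 genes of smallest p in each direction, DESeq2 called all but Bcl2l11.

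**Figure D2:**
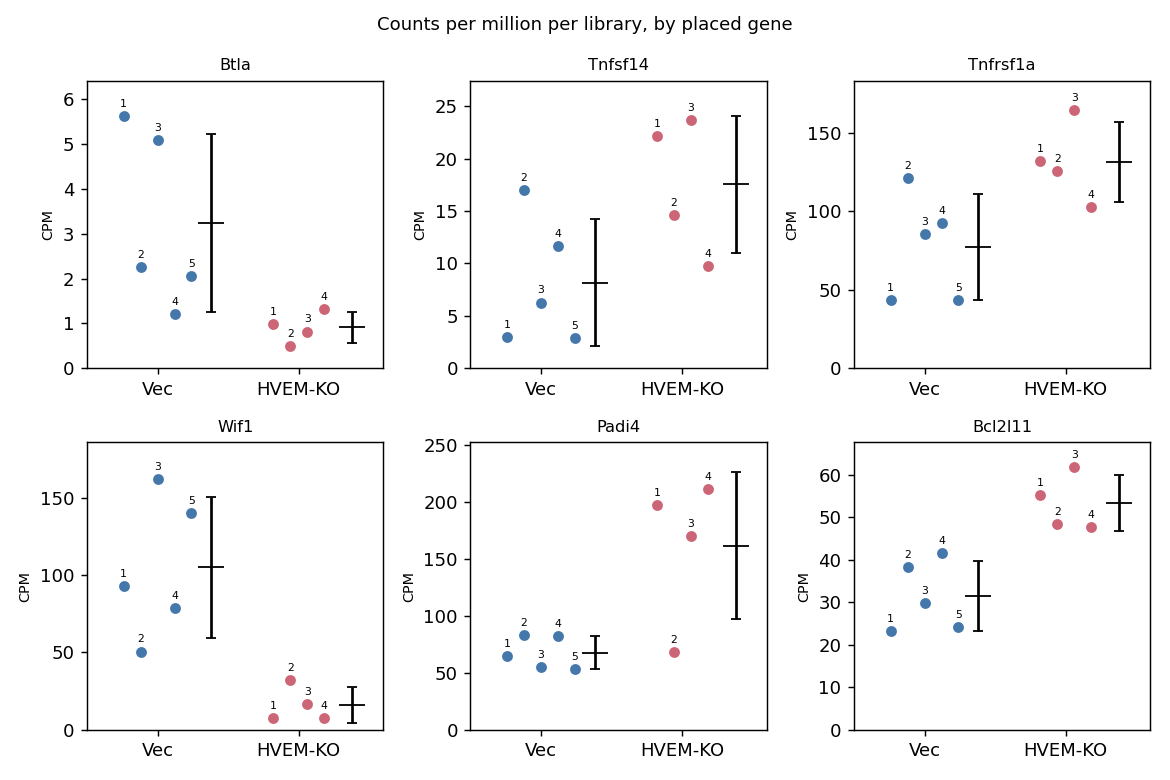
CPM (vertical axes, from 0) of 6 placed genes in Vec and HVEM-KO tumours. Points are libraries, numbered by replicate, and the black mark and bar beside them are the group mean and SD. Wif1 ran from 50.5 to 162 CPM in Vec and from 7.47 to 32.1 CPM in HVEM-KO tumours.

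Genes of the interferon gamma response and of MHC class II presentation were higher in HVEM-KO tumours as groups. All 11 measured genes of the interferon gamma response were higher, with a median log2 fold change of 0.54 (camera, adjusted p = 0.00259, and adjusted p = 0.482 with an estimated correlation). The median was 0.30 without Vec 1 and 0.31 without HVEM-KO 3, and with members found by deposited names it was -0.12 (adjusted p = 0.520). Socs1, a feedback inhibitor, was at 100.1 ± 9.46 CPM in Vec and 159.8 ± 74.6 CPM in HVEM-KO tumours, a log2 fold change of 0.68 ± 0.26. Irgm2, a GTPase, had a log2 fold change of 0.67 ± 0.31, and Gbp4, a guanylate-binding protein, one of 0.79 ± 0.51. Socs1 was at 0.39 without HVEM-KO 3 and Gbp4 at 1.34 without Vec 2. Of the 11 genes, 0 passed over all rows and 0 passed adjusted over the list alone.

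In the MHC class II list 6 of 7 members were higher, with a median of 0.64 (camera, adjusted p = 0.00371, and adjusted p = 0.482 with an estimated correlation), and of 0.40 with limma voom. The row over the class II genes H2-Aa and H2-Ab1 was at 2811 ± 1356 CPM in Vec and 4646 ± 1069 CPM in HVEM-KO tumours. H2-DMa, which helps to load peptides, had a log2 fold change of 0.77 ± 0.26, H2-Ob one of 1.20 ± 0.38 and H2-DMb2 one of 0.64 ± 0.34. Over all rows 0 members passed, and 2, H2-Ob and H2-DMa, passed adjusted over the list alone (edgeR, adjusted p = 0.0386 for both).

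Complement genes were higher in 5 of 5 members, with a median of 0.84 (camera, adjusted p = 0.00863, and adjusted p = 0.482 with an estimated correlation). C5ar1, the receptor for C5a, was at 21.3 ± 10.1 CPM in Vec and 43.4 ± 17.4 CPM in HVEM-KO tumours. C4b had a log2 fold change of 1.08 ± 0.50, C1qc, a C1q chain, one of 0.84 ± 0.42, and Cfp, which encodes properdin, one of 0.37 ± 0.25. C1qc was at 0.46 without HVEM-KO 3, and Cfp at 0.20 without HVEM-KO 2, 0.21 without HVEM-KO 3 and 0.57 without HVEM-KO 4. Of the 5, 0 passed over all rows and 0 passed adjusted over the list alone. This call was lost without HVEM-KO 2 (adjusted p = 0.0695) and without HVEM-KO 3 (0.0833, with a median of 0.46).

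Genes of the T lineage and of T cell receptor signalling, which EL4 cells themselves express, were lower in HVEM-KO tumours as a group. Of 7 members 5 were lower, with a median of -0.44 (camera, adjusted p = 0.0222, adjusted p = 0.482 with an estimated correlation, and 0.0833 without HVEM-KO 3). Without Vec 5 the median was -0.29. Lck, the kinase of the T cell receptor, was at 433 ± 98.7 CPM in Vec and 320 ± 32.5 CPM in HVEM-KO tumours. Zap70, the kinase downstream of it, was at 152 ± 19.4 and 114 ± 11.2 CPM, and the row over Cd3d and Cd3g at 1675 ± 310.3 and 1218 ± 88.7 CPM. Over all rows 0 members passed, and these 3 rows passed adjusted over the list alone (edgeR, adjusted p = 0.0471 for Lck and adjusted p = 0.0438 for the others). Thy1 had a log2 fold change of -0.51 ± 0.22 and Lat, an adaptor of the receptor, one of -0.46 ± 0.24. Without Vec 5, Lat was at -0.20 and Lck, at -0.44 with all libraries, at -0.29.

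**Figure D3:**
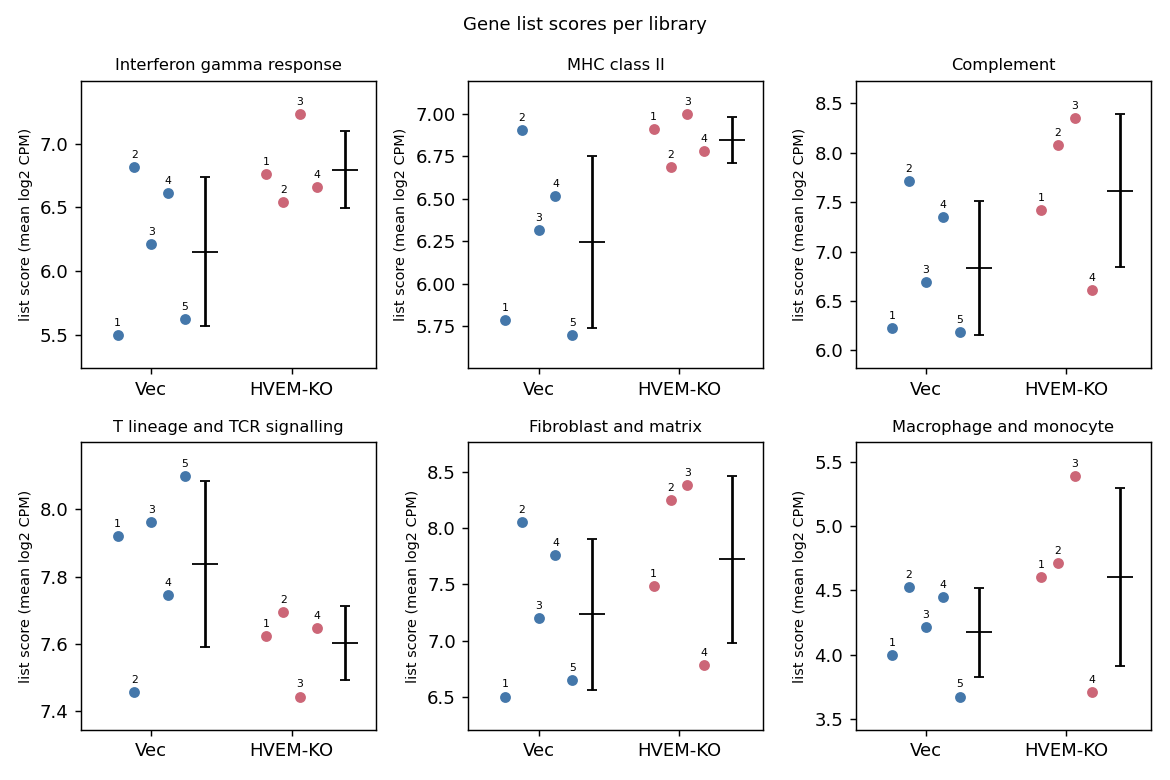
List scores (vertical axes, mean log2 CPM of the members) of 6 gene lists in Vec and HVEM-KO tumours. Points are libraries, numbered by replicate, and the black mark and bar beside them are the group mean and SD. Vec 1 and Vec 5 have the lowest interferon gamma scores, 5.5 and 5.62.

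The question of CD8 T cells could be addressed only in part. No row was placed on Cd8a, Gzmb, Prf1 or Ifng. In the CD8 cytotoxic list 4 members were measured, too few for the list test. Cd8b1, the CD8 beta chain, was at 3.14 ± 1.49 CPM in Vec and 6.05 ± 2.30 CPM in HVEM-KO tumours. The natural killer receptors Klrd1 and Klrc1 had log2 fold changes of 0.65 ± 0.33 and 0.96 ± 0.55, and the granzyme gene Gzmm one of -0.48 ± 0.42. Klrd1 was at 0.43 without Vec 5, Klrc1 at 1.45 without Vec 2, and Gzmm at -0.22 without Vec 5 or without HVEM-KO 3, -0.77 without HVEM-KO 2 and 0.02 without Vec 1 and Vec 5. Of the 4, 0 passed over all rows (edgeR, adjusted p from 0.439 to 0.673) and 0 passed adjusted over the list alone.

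Markers of other cell types were mostly at higher values in HVEM-KO tumours too, and their lists passed only in some alternatives. In the fibroblast and matrix list 9 of 11 members were higher, with a median of 0.43 (camera, adjusted p = 0.0532). The list passed with DESeq2 size factors (0.0440), with at least 1 CPM in 4 libraries (0.0460), without a low-count filter (0.0252) and without Vec 2 (0.00613), Vec 4 (0.0181), HVEM-KO 1 (0.0131) or HVEM-KO 4 (0.00169). Its median ran from 0.19 without HVEM-KO 3 to 0.85 without Vec 2, and was 0.03 without Vec 1 and Vec 5. Sparc was at 1777 ± 965.8 CPM in Vec and 2285 ± 901.4 CPM in HVEM-KO tumours, Bgn at 1373 ± 953.4 and 1843 ± 970.0 CPM, and Col5a1, Col6a2 and Pdgfrb had log2 fold changes of 1.24 ± 0.49, 0.94 ± 0.39 and 0.91 ± 0.40 (Pdgfrb 0.53 without HVEM-KO 3). The log2 fold changes of Sparc and Bgn, 0.36 and 0.42, were 0.17 and 0.18 without HVEM-KO 3, 0.69 and 0.88 without Vec 2, and -0.02 and -0.04 without Vec 1 and Vec 5. Thy1, which is also in the T lineage list, and Postn (named after its value was seen) were the 2 lower members, and 0 of the 11 passed over all rows or adjusted over the list alone. In the macrophage list 4 of 5 members were higher, C1qc among them (camera, adjusted p = 0.0994, and 0.0334 without a low-count filter). The number of lists past the threshold ran from 2 without HVEM-KO 3 to 9 without HVEM-KO 4, which added the macrophage list (0.0110) among others. Mrc1, a mannose receptor, was at 11.2 ± 1.84 and 20.3 ± 11.5 CPM (log2 fold change 0.86, and 0.49 without HVEM-KO 3), Mertk and Cd163 had log2 fold changes of 0.65 ± 0.38 and 0.76 ± 0.61 (for Cd163 0.50 without Vec 1 and 0.03 without HVEM-KO 3), and Ly6c2 one of -0.04 ± 0.34, which turned positive with library size alone.

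Vec 1 and Vec 5 stood apart from the other libraries. A multidimensional scaling was built on the tested rows that differed most between each pair of libraries, not on all rows. On its first dimension, with 37.7% of the variance of these distances, Vec 1 and Vec 5 lay at 1.36 and 1.5, and the others between -1.22 and 0.46. Their fibroblast scores, 6.50 and 6.65, were the lowest of the 9, and HVEM-KO 4 followed at 6.78. Without both, an alternative added after seeing the data, 0 rows and 0 lists passed. The interferon gamma, class II, complement and T lineage lists then had adjusted p of 0.102, 0.147, 0.204 and 0.204 (camera). Their median log2 fold changes were then 0.28, 0.34, 0.58 and -0.26. Over the alternatives with inferred names their adjusted p ran up to 0.482 and down to 2.31e-05, 2.31e-05, 0.000394 and 0.00613, and by deposited names it was 0.523 for complement and 0.386 for the T lineage list.

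Of the other lists tested, 0 passed with all libraries and the low-count filter. The adjusted p was 0.0896 for NF-kB targets (5 of 5 higher), 0.125 for immediate early genes, 0.175 for glycolysis, 0.363 for MHC class I presentation, 0.481 for mitochondrially encoded genes (8 of 12 higher) and 0.717 for hypoxia, for T cell checkpoint genes and for MYC targets. NF-kB targets passed without Vec 2 (0.0244) and without a low-count filter (0.0252), glycolysis (0.0193) and immediate early genes (0.0119) without HVEM-KO 4, and mitochondrially encoded genes without HVEM-KO 1 (0.0470) or HVEM-KO 4 (0.0321). For p53 targets the adjusted p was 0.569, with a median of -0.05 against a test direction and mean above 0. The mean of the checkpoint list, -0.02, also had the other sign than its median, 0.28, and its test. Another 21 lists had fewer than 5 tested members, with 52 members in all, of which 38 were higher and 14 lower. Of these, 0 passed over all rows and 10 passed adjusted over the list alone, the HVEM network among them and 2 as the only tested member of their list, where nothing is adjusted, and 6 lists had no tested member.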

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

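The tests of row order, of Vec 1 and Vec 5 for the gene lists, of each list alone, and the bootstrap spread of the shares left were chosen only after the results were seen. The row-order test replaced a first one that decided nothing, with 8 of 13 mitochondrial protein genes among the 1000 rows with most reads.

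In 7 of 168 groups of values, 1 library stood apart from the others of its group, where chance gives about 1 in 20, or 8.4. The gap to the nearest library, as a share of the range, was 0.951 for Hoxb8 in HVEM-KO tumours (11.8 CPM in HVEM-KO 1, 4.15 to 4.53 in the others) and 0.785 for Lck in Vec tumours (604.53 CPM in Vec 5, 362.71 to 414.6 in the others). Vec 3 was highest for Rnf19a (0.847, 363.94 CPM), Kif11 (0.765, 190.72 CPM) and Sdhb (0.760, 726.57 CPM), and lowest for Socs1 (0.729, 83.73 CPM). HVEM-KO 4 had a slope of log2 counts on GC content of -0.196 per 10% GC, against 0.149 to 0.173 in the other HVEM-KO libraries (gap share 0.935). In Vec tumours the slopes were spread from -0.336 in Vec 3 to 0.128 in Vec 5, and no library stood apart by this rule. The slope of Vec 3 was thus lower than that of HVEM-KO 4. The other HVEM-KO libraries had higher slopes than every Vec library, so the slope also differed between the groups.

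Rows named for abundant nuclear genes, such as Eef1a1 and Cd74, held no reads, while rows placed elsewhere did. Gene positions of another genome build stay a candidate explanation. With counts shuffled among rows the gain of the displaced fit was 9.48% of the real gain, under the 10% set beforehand, though by a small margin and on 3 of 20 chromosomes. These included chromosome 19, with the highest real gain per row of the 20 (0.27, against 0.159 on X, the lowest). The pass may therefore depend on which chromosomes were taken. Read the other way, the same comparison (10.5 times the gain with the real counts) argues against rows in random order, as no separate evidence, and an orderly shift of rows was not tested. No biological explanation was tested.

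The interferon gamma, MHC class II and complement lists were higher and the T lineage list lower in HVEM-KO tumours. Each library's GC slope, from the 32.7% of tested rows that were placed, was added as a covariate. Over the 4 lists together, 102% of the members' median log2 fold change was then left (bootstrap SD 14.6), above the 80% set beforehand. The lists were picked for their group difference in these same libraries, which favours a large share left. The result is thus no firm argument against GC content as the whole cause. Taken alone, class II cleared 80% (119%, 13.7), while the spread was too wide to decide for interferon gamma (76.4%, 28.1), the T lineage (95.3%, 42.7) and complement (74.9%, 27.5), of which the last lost its call (camera, adjusted p = 0.240) as its median went from 0.84 ± 0.30 (SD over members) to 0.63 ± 0.29, and the others kept theirs (0.00933 for class II and interferon gamma, 0.0453 for the T lineage). With a fibroblast and endothelial score as covariate 58.5% was left (10.7), 59.9% for interferon gamma and for class II (adjusted p = 0.0184 for both, and for mitochondrially encoded genes, then lower), 64.5% for the T lineage, whose call ended (0.281; median in the list's direction 0.44 ± 0.36 before, 0.28 ± 0.42 after), and 3.53% for complement (0.356; 0.03 ± 0.25 after), so a larger share of host tissue may account for complement and cannot be told apart from a difference between the cells for the others. Without Vec 1 and Vec 5 58.5% was also left, and chance cannot be excluded, as 44 of 100 splits, the real one included, gave as many lists (4 in the real split, 11 in the highest others, of Vec 2 with HVEM-KO 1, 2 and 3 and of Vec 2 and 4 with HVEM-KO 1 and 3), so an effect of the knockout on the tumours stays open and untested.

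DESeq2 called 83 rows, 68 of them lower in HVEM-KO tumours, where edgeR with its low-count filter called 0. Without that filter, edgeR called 70 of the 83 as well. Of the 83, 72 were tested in the filtered edgeR fit. Of their median log2 fold change, 87.9% was left without Vec 1 and Vec 5 (bootstrap SD 6.02). With the GC slope as covariate 94.1% was left (4.6), and both shares were above the 80% set beforehand. The rows were picked for their group difference in these same libraries, and in 61 of the 83 called rows the groups did not overlap. A large share left was therefore likely from the start, so neither test can argue against these causes. With the host score 84% was left (5.98), within its spread of the 80% set beforehand, so host tissue stays open. Chance cannot be excluded, as 2 of 30 splits, the real one included, gave as many rows. The highest other gave 642, for Vec 2, 3 and 4 with HVEM-KO 4, the libraries above 0 on the second scaling dimension, which points to a structure of the samples. Their GC slopes were -0.089, -0.336, 0.012 and -0.196, against -0.001 in Vec 1 to 0.173 in HVEM-KO 3 among the others. A link of this structure to GC content was not tested. A difference between the cell populations that founded the tumours may also account for rows such as that of Wif1, but it was not tested.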

How the results depend on the processing

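Leaving out both Vec 1 and Vec 5, and finding list members by deposited names, were chosen after seeing the data. Of 55 named genes 50, and of 17 lists 13, kept their direction in every alternative with inferred names. Of 16 lists also tested by deposited names, 14 had the same test direction. The interferon gamma list (median -0.119, camera, adjusted p = 0.520) and hypoxia (adjusted p = 0.896) turned to lower in the test, hypoxia with a median of 0.0172, still above 0. Placed rows mostly lay on other genes than their own, and the mitochondrially encoded rows were the same in both. The count is thus no check of the list results. No alternative gave a fold for Tnfrsf14, whose deposited row held 1 read, and the row of Btla failed the low-count filter without Vec 1, Vec 2, Vec 3 or Vec 5 and without Vec 1 and Vec 5. The fold given for Btla without Vec 1 and Vec 5 came from the rows that passed the filter with all libraries. The row count of 0 was unchanged with DESeq2 size factors, library size alone, the stricter filter, a fold of at least 2, without predicted genes and without Vec 1 and Vec 5. It was 307 (147 higher, 160 lower) without a low-count filter, 83 (15 and 68) with DESeq2 and 1 (lower) with voom. Leaving out each library gave 0 to 1 rows, 0 to 1 higher and 0 lower. Splits cannot judge a real count of 0, which 100 of 100 reached by construction (267 in the highest other). The count of lists, 4 in the main test, was 8 without a low-count filter, 5 with DESeq2 size factors and with at least 1 CPM in 4 libraries, where the fibroblast list passed too, 0 with an estimated correlation, with fry, without Vec 1 and Vec 5 and by deposited names, and 2 to 9 leaving out each library. Fewer libraries enter the fits that leave some out, and for the other alternatives the cause was not tested. Reversed log2 fold changes were, without Vec 1 and Vec 5, -0.04 for Bgn, 0.02 for Gzmm, -0.31 for Ifit2 and -0.02 for Sparc, and with library size alone 0.05 for Ly6c2. Leaving out each library, Ifit2 ran from -0.33 to 0.26 and Ly6c2 from -0.54 to 0.17. Among lists, medians where the test changed direction were, without Vec 1 and Vec 5, 0.124 for hypoxia, 0.351 for MYC targets, 0.0251 for mitochondrially encoded genes and -0.197 for p53 targets. For MYC targets they were 0.184 with voom and -0.0691 without a low-count filter. Leaving out each library, hypoxia ran from 0.0812 to 0.300, MYC targets from -0.136 to 0.103 and mitochondrially encoded genes from -0.0941 to 0.408. At this depth, 33.7% of simulated changes of log2 1 were called, so changes of that size in single rows were mostly not detectable. No paired analysis was possible because the labels give no numbers shared between the groups.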

Other observations

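The tests in this part were planned, and the lists described and the genes of the dendritic cell, neutrophil, costimulatory, endothelial and muscle lists were picked after their values were seen.

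Cell cycle genes and nuclear genes of respiration were mostly lower in HVEM-KO tumours without passing, while 8 of 12 mitochondrially encoded genes were higher, also without passing (camera, adjusted p = 0.481). In the proliferation list 4 of 5 members were lower (camera, adjusted p = 0.0896), with Mcm2, a replication helicase subunit, at 676.6 ± 106.7 CPM in Vec (SD, n = 5) and 524.5 ± 27.3 CPM in HVEM-KO tumours (SD, n = 4). The mitotic kinesins Cenpe and Kif11 had log2 fold changes of -0.31 ± 0.14 (SE) and -0.30 ± 0.18 (Kif11 -0.16 without Vec 3), and the spindle checkpoint kinase Bub1b -0.16 ± 0.12. In the oxidative phosphorylation list 6 of 7 were lower (adjusted p = 0.0909), with Cox6c, a subunit of cytochrome c oxidase, at 1090 ± 243.3 and 705.6 ± 108 CPM. Cox6c alone passed adjusted over the list alone, and 0 members of either list passed over all rows. Ndufs3 and Sdhb had log2 fold changes of -0.39 ± 0.24 and -0.20 ± 0.21, with Ndufs3 at -0.16 without Vec 5 and Sdhb at 0.00 without Vec 3, -0.10 without HVEM-KO 1 and -0.34 without HVEM-KO 4.

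Antiviral genes of the type I interferon response were higher in 4 of 4 members, too few for the list test, and 0 passed over all rows or adjusted over the list alone. Oas3 had a log2 fold change of 0.65 ± 0.25, Oas2 0.78 ± 0.45 and the RNA sensor Ddx58 0.27 ± 0.17 (Oas3 0.43 without HVEM-KO 3 and Ddx58 0.17 without Vec 5), while Ifit2 was near 0 (0.02 ± 0.44) and turned negative without Vec 1, Vec 5 or HVEM-KO 3. Of the dendritic cell list, Itgax and Cacnb3 (log2 fold changes 0.98 and 0.86) passed adjusted over the list alone (edgeR, adjusted p = 0.0215 for both). Ccl22, the other tested member, had a log2 fold change of 0.03 and did not pass (adjusted p = 0.932). Csf3r of the neutrophil list (log2 fold change 0.92) and Cd86 of the costimulatory list (0.67) were the only tested members of their lists. All 4 endothelial markers were higher, Vwf by a log2 fold change of 0.90, and skeletal muscle genes varied widely, with list scores from 3.77 in HVEM-KO 4 to 7.52 in Vec 2.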
